A study of Mus musculus with 3 samples.

How the data were processed

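Messenger RNA was measured on microarrays in 3 mouse cell populations of the C57BL/6 strain, with 1 array each. The populations were embryonic stem (ES) cells, splenic B220 B cells and splenic CD4 T cells. Per the labels, the ES cells were of the B6N-22 line and were grown on mitotically inactivated mouse embryonic fibroblasts as feeder cells, in medium with leukemia inhibitory factor. The lymphocytes came from mice aged 6 to 8 weeks and were purified with magnetic beads to a purity above 98%, per the labels' protocols. Total RNA was extracted with Trizol and labelled with biotin using the GeneChip 3' IVT Express Kit, per the labels. Whether feeder cells were removed before RNA extraction is not given in the sources used here.

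The authors deposited a table of probe set intensity values on a linear scale for 45037 probe sets, and the submitters' processing notes name Affymetrix Expression Console. Its version, the summarization algorithm, the target of the scaling and the background treatment are not given in the sources used here. The 2% trimmed means of the 3 deposited columns were 497.3 for ES cells, 497.8 for B cells and 497.7 for T cells, as arrays scaled to a common mean signal would have. The column medians were 88.8, 101.8 and 97 in the same order. Such a scaling assumes equal total signal, so a general change in mRNA content per cell cannot be seen in these values. A signal of a 3' array depends on the probes as well as on the transcript, and signals were compared between arrays for a probe set, not between probe sets.

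Probe sets were named through GEO's annotation of the array, with symbols looked up by Entrez ID in a RefSeq gene table of assembly GRCm38.p6, from which no coordinates were taken. Of the probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had no listed gene, and the last 2 kinds were kept out of the gene counts. The Entrez ID of 34741 of the 34945 was found, and 0 symbols changed. These probe sets stood for 18193 genes, of which 9183 had 1 probe set and 9010 had 2 or more. Each gene was represented by its probe set with the highest mean over the 3 arrays. The detection level was the 50th percentile of all values, a signal of 95.0, and lower values were raised to it before the log2 was taken. A fold against an array below that level is a lower bound and is written "at least". A gene was called measured in a comparison where at least 1 of the 2 arrays was above the detection level, and was counted as different where the difference was at least 4-fold and the brighter array was above that level.

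With 1 array per population there was no replicate error, no test was run and no p-value is given. The number of arrays limits the precision of every value. The only error that could be estimated was the disagreement between the 2 brightest probe sets of a gene, which covers probe effects and not differences between cultures or animals. The 3 comparisons were T cells against ES cells, B cells against ES cells and T cells against B cells, together with the count of genes at least 4-fold higher in 1 array than in both others. Because the first 2 comparisons share the ES cell array, overlaps are given beside the overlap of independent lists and beside 100 simulations of unchanged arrays that share the ES cell array, with a noise SD of 0.398 on the log2 scale.

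Before the data were examined, 25 gene lists with 451 entries, the comparisons, the thresholds and the alternatives were fixed. Of the entries, 39 had no probe set of a single listed symbol and are not analysed here. The lists covered pluripotency, T cell identity, B cell identity, MHC class II presentation, pan-lymphocyte genes, T cell homing and quiescence, helper T cell regulators, Polycomb repressive complexes 1 and 2, Trithorax complexes of the MLL and SET1 type, SWI/SNF subunits, DNA methylation, Hox genes, developmental regulators, replication and mitosis, immediate early genes, reference genes, and markers of fibroblasts, macrophages, neutrophils, erythroid cells, NK and cytotoxic cells, dendritic cells, plasma cells and platelets. For each list the median log2 difference of its measured members was computed together with its percentile among 10000 random lists of the same size matched in 20 bins on mean expression. The percentile describes these arrays and is not a test.

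The genes named were chosen by a rule fixed at the same time. It took the 12 genes with the greatest difference in each direction per comparison, skipping clone-type names and immunoglobulin and T cell receptor segments. It added up to 4 measured members of each list with the greatest absolute difference and any member at least 4-fold against its list's median. Men1, Kmt2a, Bmi1, Ezh1, Ezh2, Suz12, Eed, Rnf2, Ring1, Cbx7 and Gata3 were always included. Genes named outside the rule are marked as chosen after their values were seen.

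Alternatives were quantile normalization, scaling to the 75th percentile, no floor with 16 added before the log2, and the mean of a gene's probe sets. Others were detection levels at the 35th and 65th percentiles and thresholds of 2-fold and 8-fold. A further alternative left out probe sets whose names end in s_at or x_at. The last required every probe set of a gene to differ at least 2-fold in the same direction. That mean and that requirement took in probe sets below the detection level on both arrays, which entered as unchanged. The counting was tested on simulated data with planted changes. Without replicates, the noise of these data could not hold measured variation between cultures or animals. The shares recovered and the calls among unchanged genes thus check the computation only. They give no rate of false or missed calls for the counts reported below. For T cells against ES cells over 11828 genes, 96% of genes planted at 8-fold and 100% at 16-fold were recovered, with 4 calls among unchanged genes. For B cells against ES cells over 11824 genes the shares were 98% and 100%, with 3 such calls, and for T cells against B cells over 10951 genes they were 98% and 100%, with 5. Of 40 unchanged lists, 4, 0 and 2 lay outside the central 95% of random lists in the 3 comparisons. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.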

Results

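Messenger RNA levels were compared between ES cells, splenic B cells and splenic CD4 T cells of the mouse, with 1 array per population. Of 18193 genes, 10967 (60.3%) were above the detection level in ES cells, 10509 (57.8%) in B cells and 10329 (56.8%) in T cells. The highest signals were 51771, 58060 and 43544 in the same order. Across genes, the log2 signals of T cells and B cells had a Pearson correlation of 0.885 and a Spearman correlation of 0.879 over 11194 measured genes. T cells and ES cells had correlations of 0.578 and 0.537 over 12325 genes, and B cells and ES cells 0.586 and 0.543 over 12463 genes. Genes are not independent replicates, and these values describe 3 arrays. No difference below has a replicate check.

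The first comparison asked how mRNA levels in CD4 T cells differed from those in ES cells. Genes of lymphocyte identity were higher in T cells. Cd3d, a chain of the T cell receptor complex, was at least 180-fold higher, with signals of 17144 in T cells and 6 in ES cells. Ptprc, which encodes the leukocyte surface phosphatase CD45, was at least 281-fold higher. Genes of the pluripotent state were lower. Dppa5a was at least 493-fold lower, with a signal of 46811 in ES cells, and Pou5f1, which encodes the pluripotency factor Oct4, was at least 163-fold lower. In all, 1332 genes were at least 4-fold higher in T cells and 1252 at least 4-fold lower, of 12325 measured, and 52.6% of measured genes lay within 2-fold.

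Other genes high in T cells relative to ES cells included surface and signalling genes of lymphocytes. Ms4a4b was at least 300-fold higher, Cd52 at least 269-fold, Gimap4 at least 244-fold, Cytip at least 230-fold and Ms4a6b at least 200-fold. H2-Aa, an MHC class II chain, was at least 196-fold higher, Mndal at least 172-fold, Gimap8 at least 145-fold and Cd53 140-fold. Kbtbd11 was 167-fold higher, but its probe sets ranged from 0.25 to 7.38 on the log2 scale. Among genes lower in T cells, Bex1 was at least 280-fold lower, Rps4l 179-fold, the matrix genes Fn1 and Col1a2 at least 169-fold and 167-fold, Tdgf1 at least 165-fold and L1td1 163-fold. Gja1, a gap junction gene, was at least 153-fold lower, the small heat shock gene Hspb1 143-fold and the metallothionein gene Mt2 133-fold. Enah was at least 179-fold lower by its brightest probe set, while another of its probe sets gave -0.13 on the log2 scale.

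By list, all 23 measured pluripotency genes were at least 4-fold lower in T cells, with a median log2 difference of -5.12. Members below the detection level enter a median at that level, and 17 of the 25 medians in this comparison move with such members. Those of pluripotency, T cell identity and pan-lymphocyte genes are therefore bounds. Of 23 T cell identity genes, 22 were at least 4-fold higher and 0 lower, with a median of 5.23. Besides Cd3d, the examples with the greatest differences were Cd3g and the interleukin-7 receptor gene Il7r, each at least 135-fold higher, and Cd5 at least 107-fold. All 20 pan-lymphocyte genes were at least 4-fold higher, with a median of 6.29, among them Rac2 at least 121-fold, or 1.63 on the log2 scale by its other probe set. Of 14 homing and quiescence genes, 12 were at least 4-fold higher and 0 lower, with a median of 3.97. The chromatin organizer gene Satb1 was 95.9-fold higher (1.98 on the log2 scale by its lowest probe set), the lymph node homing receptor gene Ccr7 at least 77.3-fold and Slfn2 47.7-fold. Of 16 helper T cell genes, 11 were at least 4-fold higher and 0 lower, with a median of 3.09, including Ikzf2 at 49.7-fold, Maf at 35.2-fold, Gata3 at least 13.2-fold and the cytokine gene Ifng at least 12.7-fold.

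Some genes of other immune cells were also higher in the T cell array than in the ES cell array. Of 20 measured B cell identity genes, 11 were at least 4-fold higher and 0 lower, with a median of 2.02, led by Ighm at least 211-fold, with probe sets from 0.35 to 7.92 on the log2 scale, and Ms4a1 at least 23.2-fold, with Bank1 at least 17.7-fold and Pou2af1 at least 15.5-fold. Of 11 MHC class II genes, 10 were at least 4-fold higher, with a median of 4.51, among them H2-Ab1 at least 71.8-fold, Cd74 53.4-fold and H2-Eb1 37.9-fold. In the same array 12 of 14 macrophage markers were at least 4-fold higher, with a median of 4.05. Csf1r, the receptor for macrophage colony-stimulating factor, had a signal of 19275 and was 92.3-fold higher, and the complement genes C1qa and C1qb were 63.1-fold and 49.2-fold higher. Of 12 NK and cytotoxic cell markers 8 were at least 4-fold higher, with a median of 2.51, and Ccl5 was at least 44.7-fold and Klrd1 at least 24.8-fold higher. Of 10 dendritic cell markers 4 were at least 4-fold higher, with a median of 1.69, of 9 neutrophil markers 3, with a median of 1.20, and of 7 plasma cell markers 3, with a median of 1.08. S100a8 was at least 94.2-fold higher, Jchain at least 101-fold higher and Sdc1, against its list, 12.5-fold lower, with a probe set at -0.98.

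Most listed cell cycle and fibroblast genes were lower in T cells than in ES cells. Of 24 replication and mitosis genes, 16 were at least 4-fold lower and 0 higher, with a median of -2.55. Ccne1 was 21.8-fold lower, the mitotic kinase gene Cdk1 20.8-fold, Bub1 19.9-fold, or -1.83 on the log2 scale by its other probe set, and Aurka 12.8-fold. Of 19 fibroblast markers, 16 were at least 4-fold lower and 0 higher, with a median of -3.92, among them Tagln at least 91.3-fold and Acta2 81.3-fold. Of 17 immediate early genes, 12 were at least 4-fold higher, with a median of 2.86. Dusp2 was at least 64.4-fold higher, Cd69 at least 49.1-fold, Zfp36 18.6-fold and Junb 18.2-fold, and Ier3 was 5.51-fold lower. Of 1332 higher genes 587, and of 1252 lower genes 621, rested on a lower bound, and 784 lower genes were counted with the detection level at the 65th percentile and also 784 where every probe set had to differ. With scaling to the 75th percentile, which put the median of all genes at -0.42 in place of -0.11, the share of counted genes that were higher in T cells was 38.6% in place of 51.5%.

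The second comparison asked how B cells differed from ES cells. B cell receptor and MHC class II genes were higher in B cells. Cd79b, a signalling chain of the B cell receptor, was at least 334-fold higher with a signal of 31707, and the B cell surface gene Ms4a1 was at least 347-fold higher. H2-Aa was at least 486-fold and H2-Ab1 at least 382-fold higher. Dppa5a was at least 493-fold and Pou5f1 at least 163-fold lower. In all, 1227 genes were at least 4-fold higher in B cells and 1289 at least 4-fold lower, of 12463 measured, and 54.3% of measured genes lay within 2-fold.

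Other genes high in B cells were Cd52 at least 375-fold, Ptprc at least 322-fold, Cd74 268-fold, Ly6d at least 252-fold, Fcmr, which encodes the Fc receptor for IgM, at least 244-fold, Mndal at least 235-fold, H2-DMb2 at least 224-fold and Btla at least 216-fold. Genes lower in B cells included Bex1 at least 280-fold, Mt2 212-fold, Enah at least 179-fold, again with a probe set at -0.13, Col1a2 at least 167-fold, Tdgf1 at least 165-fold and Gja1 at least 153-fold. Hspb1 was 138-fold lower, Gsta4 at least 135-fold, Fabp3 132-fold, though its other probe set gave -0.61 on the log2 scale, and the matricellular gene Ccn2 at least 125-fold.

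All 21 measured B cell identity genes were at least 4-fold higher in B cells, with a median log2 difference of 6.58, including Ighm at least 486-fold and Bank1 at least 186-fold. That median is a bound in the same sense, and 19 of the 25 medians in this comparison move with members below the detection level. All 11 MHC class II genes were at least 4-fold higher, with a median of 7.07, and all 20 pan-lymphocyte genes, with a median of 5.83 and Coro1a at 130-fold. Of 18 measured T cell identity genes, 1 was at least 4-fold higher, 1 was at least 4-fold lower and 16 were neither, with a median of 0.77. The first was Cd2, at least 68.3-fold higher, and the second was Thy1, 11.2-fold lower with a signal of 1180 in ES cells. Of 14 homing and quiescence genes 10 were at least 4-fold higher, with a median of 3.18, led by Ccr7 at least 48.6-fold and Ccr6 45.5-fold. Of 8 helper T cell genes 5 were at least 4-fold higher, with a median of 2.17. The follicular homing receptor gene Cxcr5 was at least 66.9-fold higher and Bcl6 10.1-fold, or 1.53 on the log2 scale by its other probe set. Of 23 pluripotency genes 22 were at least 4-fold lower, with a median of -5.51, and the exception, chosen after its value was seen, was Klf4 at -1.25.

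Of 24 replication and mitosis genes, 13 were at least 4-fold lower in B cells than in ES cells and 0 higher, with a median of -2.13. Ccne1 was 15.5-fold lower and Bub1 15.3-fold, or again -1.83 on the log2 scale by its other probe set. Of 17 immediate early genes, 11 were at least 4-fold higher, with a median of 3.35. Dusp2 was at least 87.2-fold and Cd69 at least 48.8-fold higher, and Ier3 was 19.3-fold lower. Of 19 fibroblast markers 17 were at least 4-fold lower, with a median of -5.03. Of 15 macrophage markers 8 were at least 4-fold higher, with a median of 2.16, and the signal of Csf1r was 8930. Plasma cell markers had a median of 0.62, with 3 of 7 at least 4-fold higher, namely Mzb1 at least 154-fold, Jchain at least 137-fold and Irf4 at least 28.6-fold, or 0.93 on the log2 scale by its other probe set. NK and cytotoxic cell markers had a median of 1.35, with 4 of 12 at least 4-fold higher. The medians were 0.61 for neutrophil, 0.43 for dendritic cell and 0.83 for platelet markers. Of 1227 higher genes 509, and of 1289 lower genes 668, rested on a lower bound, and 799 lower genes were counted with the detection level at the 65th percentile and 798 where every probe set had to differ. With scaling to the 75th percentile, which put the median of all genes at -0.37 in place of -0.07, the share of counted genes that were higher in B cells was 37.4% in place of 48.8%.

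**Figure D1:**
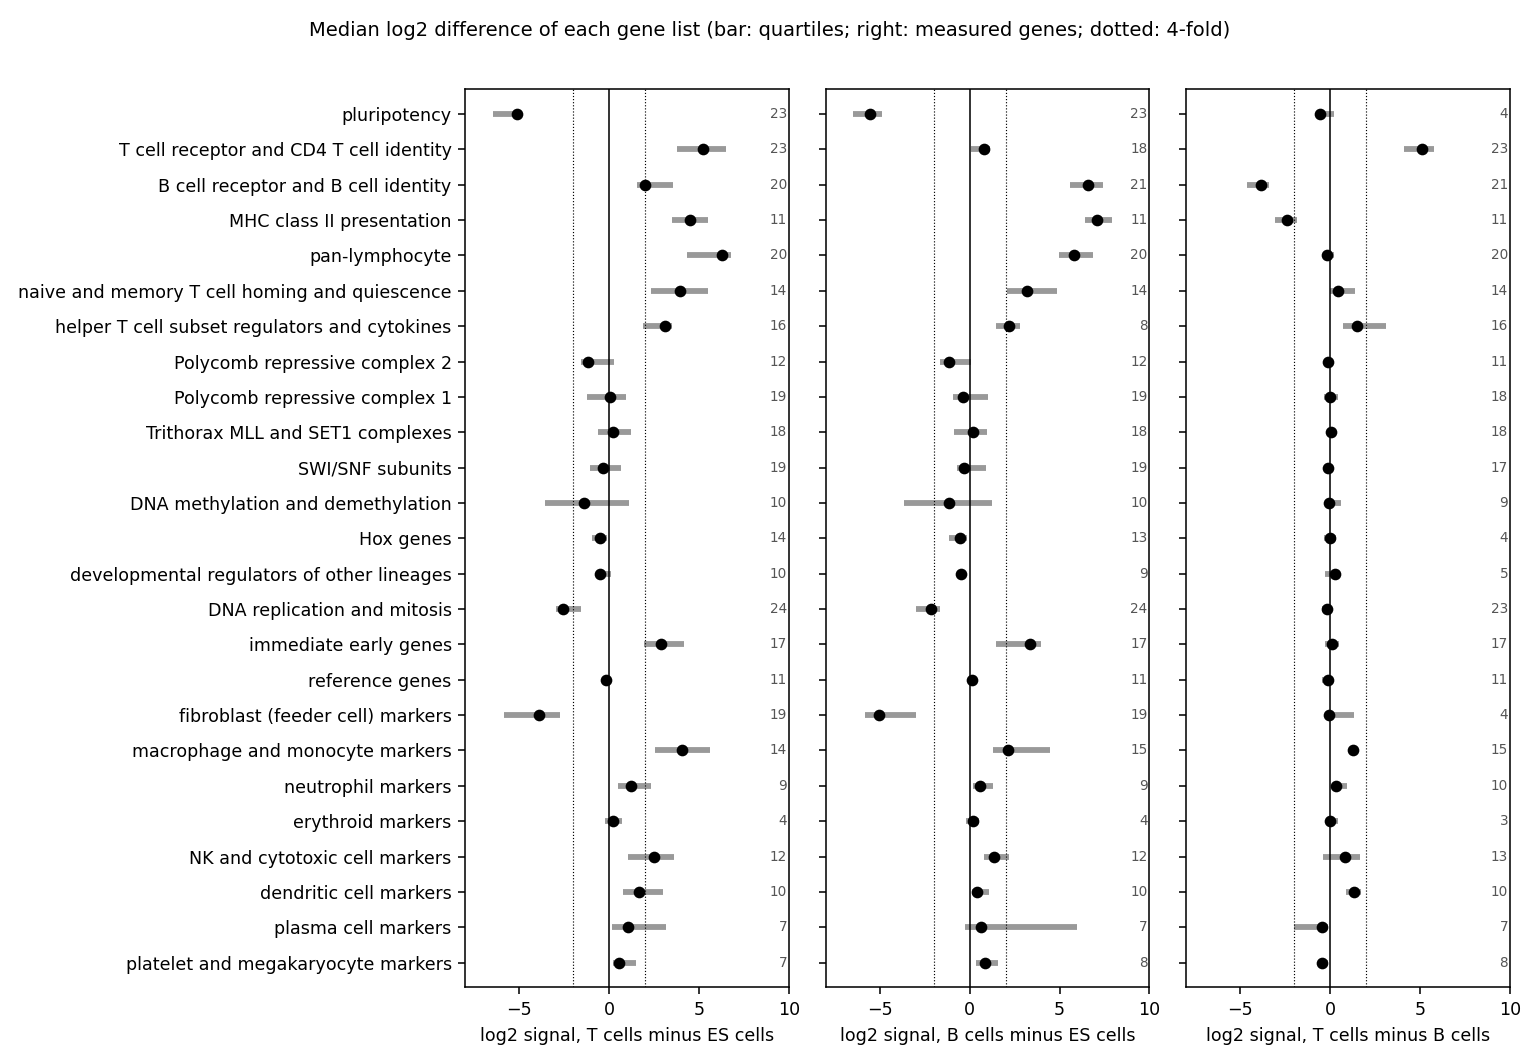
Median log2 difference (points) and quartiles (bars) of the measured members of the 25 gene lists in the 3 comparisons, with the number of measured genes at the right and dotted lines at 4-fold. Pluripotency genes lie at -5.12 and -5.51 against ES cells, and in T cells against B cells T cell identity genes lie at 5.13 and B cell identity genes at -3.87. With scaling to the 75th percentile the medians near 0 of the Trithorax, reference (B cells) and erythroid lists against ES cells, of both T cell comparisons of Polycomb repressive complex 1 and of erythroid markers in T cells against B cells change sign.

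The third comparison set T cells against B cells and asked which genes separated the 2 lymphocyte populations. Genes of the T cell receptor complex and of T cell regulation were higher in T cells, and genes of B cell identity were lower. The transcription factor gene Bcl11b was 98.6-fold higher, with signals of 10349 in T cells and 105 in B cells, and Cd3g was 78.6-fold higher. Ebf1, a transcription factor gene of the B lineage, was 38.3-fold lower, although its probe sets ranged from -5.26 to -0.41 on the log2 scale, and Cd79b was 28.9-fold lower. In all, 279 genes were at least 4-fold higher in T cells and 207 at least 4-fold lower, of 11194 measured, and 84.8% of measured genes lay within 2-fold.

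Other genes high in T cells were Thy1 at 68.0-fold, Cd5 at 61.2-fold, Ikzf2 at least 59.8-fold, the kinase gene Prkcq at least 56.9-fold, the costimulatory receptor gene Cd28 at 56.2-fold, Il7r at 54.8-fold, Lef1 at 47.5-fold, Cd3d at 47.1-fold and Igfbp4 at 46.5-fold. Cd247 was 59.5-fold higher, although one of its probe sets gave -0.06 on the log2 scale. Genes lower in T cells were Serpinb1a at 52.2-fold, the low-affinity IgE receptor gene Fcer2a at 47.6-fold, Srpk3 at 44.0-fold, the fatty acid desaturase gene Scd1 at 40.9-fold and Haao at least 31.6-fold. The complement receptor gene Cr2 was 31.3-fold lower, Fcmr 30.7-fold, Dennd5b 29.0-fold (-1.83 on the log2 scale by another probe set), the BAFF receptor gene Tnfrsf13c 28.3-fold and Siglecg 25.3-fold.

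Of 23 T cell identity genes, 21 were at least 4-fold higher in T cells than in B cells and 0 lower, with a median log2 difference of 5.13. That median is a bound, and 8 of the 25 medians here move with members below the detection level. Of 21 B cell identity genes, 19 were at least 4-fold lower and 0 higher, with a median of -3.87. Of 11 MHC class II genes, 7 were at least 4-fold lower, with a median of -2.41, including H2-DMb2 at 18.8-fold, H2-Oa at 9.37-fold, the class II transactivator gene Ciita at 8.75-fold (-1.43 on the log2 scale by another probe set) and H2-Ob at 7.84-fold. Of 16 helper T cell genes, 7 were at least 4-fold higher, with a median of 1.52, including Gata3 at least 13.2-fold, Pdcd1 at least 10.3-fold and Ifng at 9.06-fold, and Cxcr5 was 6.40-fold lower. Of 14 homing and quiescence genes, 3 were at least 4-fold higher, with a median of 0.44, among them Cxcr3 at 6.76-fold, and Ccr6 was 10.4-fold lower. Pan-lymphocyte genes had a median of -0.17, and 1 of 20, Cd37, was at least 4-fold lower, at 5.32-fold. Of 7 plasma cell markers 2 were at least 4-fold lower, Mzb1 at 10.7-fold and Irf4 at 4.98-fold, or -0.93 by its other probe set, with a median of -0.43.

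Of 15 macrophage markers, 0 reached 4-fold between T cells and B cells. Their median log2 difference was 1.25, with quartiles of 1.09 and 1.31, and 14 had a positive difference, the exception, chosen after its value was seen, being Itgam at -0.09 as a bound. Lyz2 was 3.32-fold higher, Cd163 2.99-fold, Vcam1 2.58-fold and Cd14 2.49-fold. Dendritic cell markers had a median of 1.34, with 1 of 10 at least 4-fold higher, Ccr9 at 9.61-fold, or 1.97 on the log2 scale by another probe set. NK and cytotoxic cell markers had a median of 0.83, with 2 of 13 at least 4-fold higher, Il2rb at least 11.9-fold and the CD8 chain gene Cd8b1 at 4.32-fold. Their lower quartile was -0.41, and the members below 0, chosen after their values were seen, were Gzma at -1.64, Klre1 at -1.20, Ncr1 at -0.83 as a bound and Cd8a at -0.41. Medians were 0.35 for neutrophil and -0.43 for platelet markers, with 0 of 10 and 0 of 8 at 4-fold. Of 4 measured fibroblast markers, S100a4 was 41.5-fold higher in T cells. Of 23 replication and mitosis genes and of 17 immediate early genes 0 reached 4-fold, with medians of -0.19 and 0.10, and of 4 pluripotency genes Tet1 was at least 5.79-fold higher in T cells. With the detection level at the 65th percentile, 166 genes in place of 279 were counted higher in T cells.

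**Figure D2:**
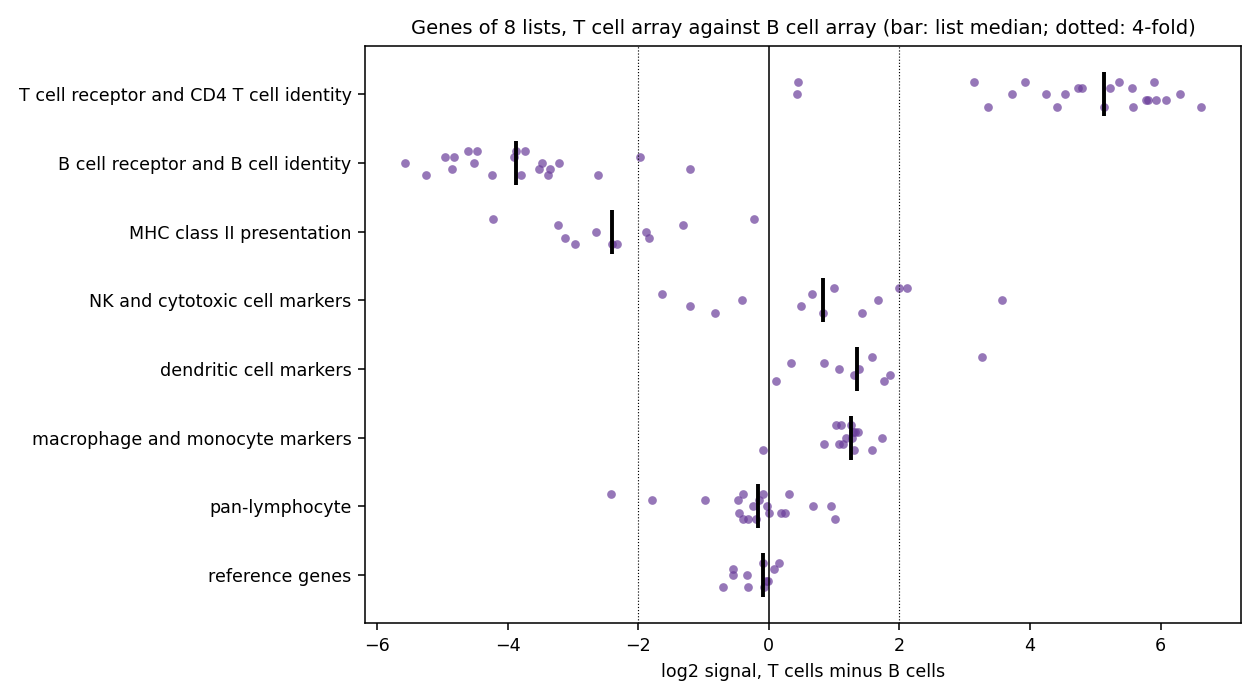
Log2 difference of each measured gene of 8 lists (points) between the T cell and the B cell array, with list medians (bars) and dotted lines at 4-fold. T cell identity genes have a median of 5.13, B cell identity genes of -3.87 and MHC class II genes of -2.41, and macrophage markers have a median of 1.25 with quartiles of 1.09 and 1.31.

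Taking the 3 arrays at once, 1056 genes were at least 4-fold higher in ES cells than in both lymphocyte populations, 168 in B cells than in both others and 185 in T cells than in both others. ES cells were at least 4-fold below both lymphocyte populations for 908 genes, B cells below both others for 51 and T cells for 21. With the detection level at the 65th percentile, 662 genes were highest in ES cells and 117 in T cells, and 656 were highest in ES cells where every probe set had to differ. Of 12012 genes measured against ES cells in both comparisons, 1277 were counted higher in T cells and 1204 in B cells, and 908 in both, where independent lists would share 128. For lower genes the counts were 1252 and 1289, with 1056 in both, where independent lists would share 134. Simulated unchanged arrays with a shared ES cell array gave means of 0.04 and 0.03 shared genes and at most 1. Their noise came from the disagreement of probe sets alone, at which 4-fold differences hardly occur. The simulations thus leave out variation between cultures or animals and give no usable comparison for the overlaps. The ES cell array could not be split, and part of the overlap may come from its use in both comparisons. Macrophage markers also lay at least 4-fold above ES cells in both lymphocyte arrays, 12 of 14 in T cells and 8 of 15 in B cells. Other cells present in both lymphocyte samples may thus add to the 908 shared genes and to the counts of higher genes, which was not tested.

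Of 49 measured Polycomb and Trithorax genes, which the series title names, 10 (20.4%) differed by at least 4-fold between T cells and ES cells and 8 (16.3%) between B cells and ES cells, against 21.0% and 20.2% of all measured genes. Of the 47 measured between T cells and B cells 0 differed by 4-fold, against 4.34% of all measured genes, a share at which 0 does not set so few genes apart. The counts against ES cells depend on the scaling, as given below. Ezh2, the methyltransferase of Polycomb repressive complex 2, had signals of 4769 in ES cells, 1449 in B cells and 1931 in T cells, and was 3.29-fold lower in B cells and 2.47-fold lower in T cells than in ES cells. Its paralog Ezh1 was 4.82-fold higher in B cells and 4.59-fold higher in T cells. Bmi1, a component of Polycomb repressive complex 1, was 4.36-fold and 4.63-fold higher. Kmt2a, the methyltransferase also called MLL1, was 3.91-fold and 4.23-fold higher in B cells and T cells, and its other probe set gave 1.70 and 1.41 on the log2 scale. The signal of Men1, which encodes the menin subunit of MLL complexes, was 463 in ES cells, 484 in B cells and 423 in T cells, while its probe sets ranged from -0.13 to 0.96 on the log2 scale in T cells and from 0.05 to 1.11 in B cells against ES cells.

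Polycomb repressive complex 2 had a median log2 difference of -1.15 in T cells against ES cells, at percentile 1.33 of random lists, and of -1.13 in B cells, at percentile 1.62. The percentiles were 61.5 and 19.3 for Polycomb repressive complex 1 and 68.2 and 64.6 for Trithorax genes, and 4 of 40 unchanged lists in the simulated data lay outside the central 95% in T cells against ES cells. Of its 12 genes, 2 were at least 4-fold higher and 2 at least 4-fold lower in T cells. The higher ones were Phf1 at 5.52-fold and Ezh1, and the lower ones Epop at least 5.04-fold and Jarid2 at 4.93-fold. In B cells Phf1 was 4.79-fold higher and Epop at least 5.04-fold lower. The core subunit gene Eed was 2.68-fold lower in T cells and 2.44-fold lower in B cells, where its other probe set gave 0.07 on the log2 scale. Suz12 was 2.33-fold and 2.12-fold lower, although its probe sets in T cells against ES cells ranged from -1.22 to 0.82 on the log2 scale. The probe sets of Ezh1 ranged from 0.81 to 2.20 in T cells and from 0.45 to 2.27 in B cells. When the mean of the Ezh1 probe sets was taken, its difference was 0.75 on the log2 scale in T cells and 0.68 in B cells. That mean took in 4 probe sets, of which only 2 were measured, and the rest entered as unchanged. It was thus pulled toward no change and is no separate estimate for Ezh1. With the mean of probe sets the medians of Polycomb repressive complex 2 were -0.71 in T cells and -0.65 in B cells.

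Of 19 Polycomb repressive complex 1 genes, 2 were at least 4-fold higher and 1 lower in T cells than in ES cells, with a median of 0.06, and 2 were higher and 2 lower in B cells, with a median of -0.39, which was 0.14 with the mean of probe sets. Phc1 was 12.5-fold lower in T cells and 12.9-fold lower in B cells, Phc3 was 6.20-fold and 5.42-fold higher (0.63 on the log2 scale by its other probe set in T cells), and L3mbtl2 was 3.47-fold and 4.77-fold lower. Rnf2 was 1.28-fold and 1.76-fold lower and Ring1 2.18-fold and 2.88-fold higher, but the direction of Rnf2 turned with the probe set, from -0.51 to 0.33 in T cells and from -0.81 to 0.51 in B cells. Cbx7 was 1.04-fold higher in T cells, with probe sets from -0.23 to 0.81, and 1.35-fold higher in B cells. Of 18 Trithorax genes, 1 was at least 4-fold higher, Kmt2a, and 2 were lower in T cells, with a median of 0.22, and 1 was lower in B cells, with a median of 0.18. Ash2l was 6.12-fold lower in T cells and 6.31-fold lower in B cells, but its other probe set gave -1.04 and -0.40 on the log2 scale. Wdr5 was 4.56-fold and 3.12-fold lower, and Dpy30 3.88-fold and 3.39-fold lower. With scaling to the 75th percentile the Trithorax medians were -0.16 in T cells and -0.17 in B cells, the Polycomb repressive complex 1 median in T cells was -0.32, and Cbx7 in T cells and Men1 in B cells also changed sign, while the difference of Kmt2a was 1.70 in T cells and 1.62 in B cells. That scaling lowered the differences of detected genes by a common amount within each comparison against ES cells. It took Ezh1 and Bmi1 in both populations, and Phf1 in B cells, below 4-fold. Genes that it took to at least 4-fold lower, chosen after their values were seen, were Mtf2, Dpy30, L3mbtl2, Pcgf3 and Scmh1 in T cells and Ezh2 and Dpy30 in B cells. The balance of higher and lower genes thus rests on the scaling. The Polycomb repressive complex 1 median in T cells, Cbx7 in T cells and Men1 in B cells also changed sign with quantile normalization, where that median was -0.04.

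Between T cells and B cells the medians were -0.13 for Polycomb repressive complex 2, at percentile 24.6 of random lists, 0.01 for Polycomb repressive complex 1, where scaling to the 75th percentile gave -0.02, and 0.04 for Trithorax genes. Phf19 was 2.03-fold lower in T cells, Aebp2 1.64-fold higher, Jarid2 1.59-fold lower and Ezh2 1.33-fold higher. Cbx6 was 1.86-fold and Pcgf5 1.62-fold higher in T cells, and the chromatin-binding gene Psip1 1.69-fold higher. Bmi1, Kmt2a, Ezh1, Suz12, Eed and Men1 differed by 1.06-fold, 1.08-fold, 1.05-fold, 1.10-fold, 1.10-fold and 1.14-fold, and the first 4 of them and Rnf2 had probe sets of both signs. In this comparison the 2 brightest probe sets of a gene disagreed by a median of 0.30 on the log2 scale.

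**Figure D3:**
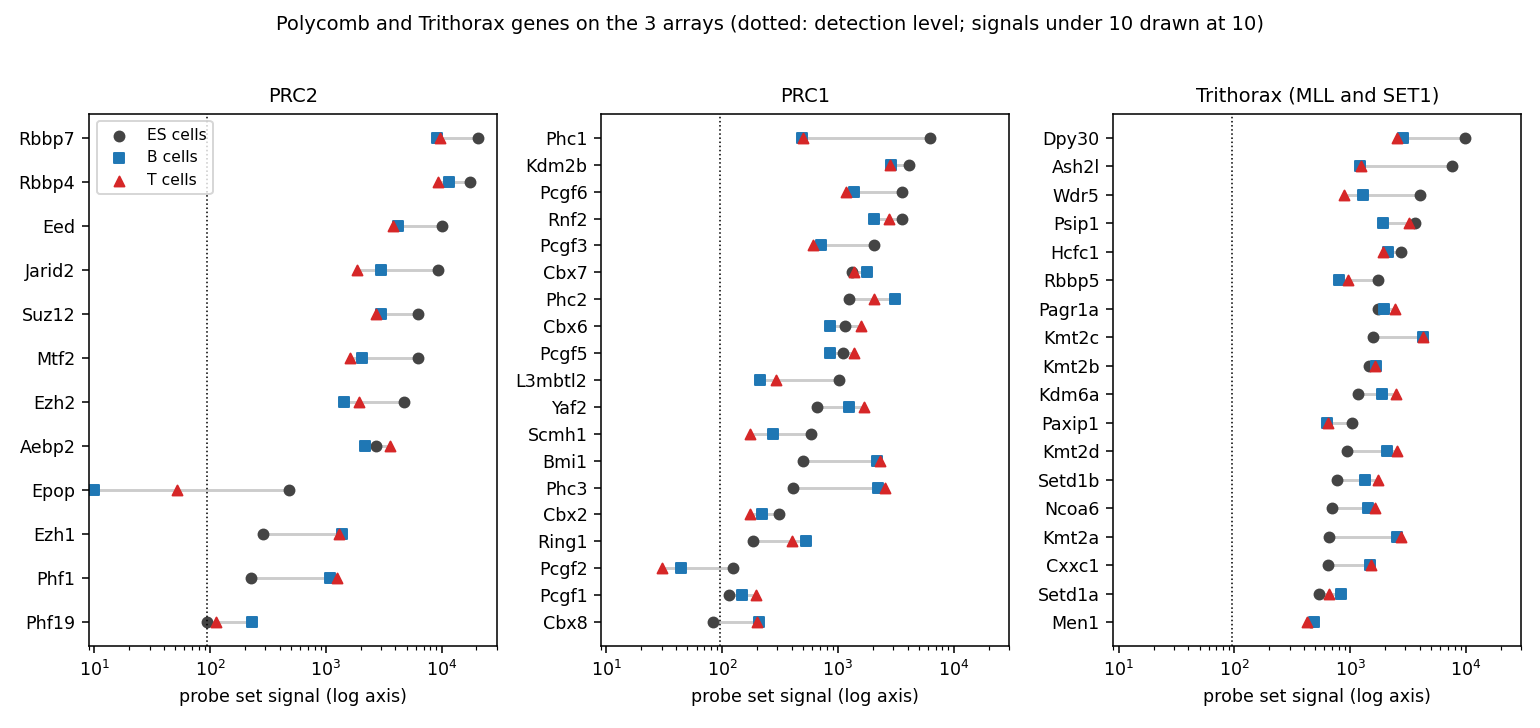
Probe set signals on a logarithmic axis of the Polycomb repressive complex 2, Polycomb repressive complex 1 and Trithorax genes in ES cells (circles), B cells (squares) and T cells (triangles), 1 array each, ordered by the ES cell signal, with the detection level of 95.0 dotted. Ezh2 lies at 4769 in ES cells against 1449 and 1931 in B cells and T cells, and Bmi1 at 498 against 2171 and 2308.

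Genes of DNA methylation and of SWI/SNF complexes were also compared. Of 10 DNA methylation and demethylation genes, 4 were at least 4-fold lower and 2 higher in T cells than in ES cells, with a median of -1.42, and 4 were lower and 1 higher in B cells, with a median of -1.17. Dnmt3l was at least 80.8-fold lower in both, the de novo methyltransferase gene Dnmt3b 12.9-fold lower in T cells and 13.9-fold in B cells, Tet1 12.4-fold and at least 71.7-fold (-0.73 on the log2 scale by another probe set in both), and Uhrf1 9.89-fold and 9.17-fold. Mbd2 was 7.28-fold and 4.77-fold higher. Dnmt3a was 5.32-fold higher in T cells, where its probe sets ranged from -1.72 to 2.41 on the log2 scale. Of 9 of these genes measured in T cells against B cells, Tet1 alone reached 4-fold, with probe sets from 0.68 to 2.53. Of 19 SWI/SNF genes, 1 was at least 4-fold higher and 0 lower in T cells against ES cells, with a median of -0.36, and 2 were higher in B cells, with a median of -0.34. Smarca2 was at least 26.6-fold higher in T cells and at least 16.5-fold in B cells, where its other probe set gave 2.19 and 1.97 on the log2 scale, and Smarcc2 was 4.40-fold higher in B cells. Between T cells and B cells the SWI/SNF median was -0.11.

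Most Hox genes and developmental regulators were below the detection level on each array, which depends on the probes as well as on the transcript. Of 33 Hox genes, 12 were above the detection level in ES cells, 2 in B cells and 3 in T cells, and the highest signal in ES cells was 288. Hoxb2 was at least 3.03-fold lower in T cells and in B cells. Hox medians were -0.50 in T cells and -0.51 in B cells against ES cells, and 0 Hox genes reached 4-fold. Of the developmental regulators 1, Olig2, was at least 4-fold lower in both lymphocyte populations, at least 4.68-fold. Their medians were -0.51 in T cells and -0.46 in B cells, with 8 of 10 and 6 of 9 measured members at a bound.

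Reference genes had medians of -0.16 in T cells against ES cells, 0.11 in B cells against ES cells, which was -0.24 with scaling to the 75th percentile, and -0.09 in T cells against B cells. Of 11, Pgk1, a glycolytic enzyme gene, was the only one at 4-fold, 4.81-fold lower in T cells, where another probe set gave -1.70 on the log2 scale, and 4.77-fold lower in B cells than in ES cells. Erythroid markers had medians of 0.20, 0.19 and 0.02 in the 3 comparisons over 4, 4 and 3 genes, all of which were negative with scaling to the 75th percentile, and platelet markers had a median of 0.53 in T cells against ES cells, where Itgb3 was 7.83-fold higher, or 0.31 on the log2 scale by its other probe set. As a measure of error, the difference of a gene between T cells and ES cells had a robust SD of 0.56 on the log2 scale between its probe sets, that between B cells and ES cells 0.53 and that between T cells and B cells 0.32. Among counted genes with several probe sets, 29 of 732 higher and 36 of 620 lower genes in T cells against ES cells had a probe set in the opposite direction, 20 of 657 and 56 of 649 in B cells against ES cells, and 10 of 158 and 1 of 90 in T cells against B cells.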

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

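The tests of lineage regulators, of scaling, of the spread of macrophage genes and of the B cell genes other than Ighm and the T cell genes other than Cd2, and the choice to leave out genes below the detection level, were chosen after the results they bear on had been seen, as were the genes named here for their place in a range. A set of 5 genes drew attention because the T cell array lay at least 4-fold above and the B cell array at least 4-fold below the ES cell array, and with 1 array each this difference was not tested. On the log2 scale, T cells minus ES cells and B cells minus ES cells were 2.58 and -2.95 for Igfbp4, 2.39 and -2.17 for Pxylp1, 2.00 and -2.75 for Tesc, 2.34 and -2.11 for Tgfbr3, and 2.61 and -3.48 for Thy1. The B cell signals of Pxylp1, Tesc and Tgfbr3 were below the detection level, so their negative values are bounds. Igfbp4 had 6 probe sets, Pxylp1 3, Tesc 2, Tgfbr3 2 and Thy1 1, and the values are of the probe set with the highest mean only. Both differences of a gene rest on the ES cell signal, which may hold RNA of feeder cells, and this was not tested for these genes. The signals of Thy1 were 1180 in ES cells, 106 in B cells and 7185 in T cells. The reverse order, lower in T cells and higher in B cells than in ES cells, was seen for 0 genes.

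Fibroblast markers stood high in the ES cell array. Of 6 interstitial matrix genes chosen beforehand, Col1a1, Col1a2, Col3a1, Dcn, Lum and Postn, 6 were above the detection level in ES cells, with signals from 519 to 15844, and at least 4-fold above both lymphocyte arrays, which is what RNA of the feeder fibroblasts named in the labels would give. These 6 genes are members of the fibroblast marker list, so they restate its high signal and are no separate support for this source. Their signals in the lymphocyte arrays were at most 80.9, below the detection level, so the second condition added little. Of 20 fibroblast markers, 0 are in another list. Expression by the ES cells themselves or by differentiated cells among them stays open: 6 of 10 lineage regulators were above the detection level, but the highest, Eomes at 419.9, had 334.8 in B cells and 470.6 in T cells, and the next, Gata6, lay at 243.4, so these genes say little about differentiated cells. The 2 sources cannot be told apart without an array of feeder cells or of ES cells grown without them, and part of the 1056 genes highest in the ES cell array may come from feeder cells.

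Genes of each sorted lymphocyte population had signal in the array of the other. Over 27 bright B cell and MHC class II genes, the T cell signal had a median of 8.75% of the B cell signal, from 2.10% for Fcer2a to 43.4% for Ighm. The highest ratio was 20.7 times the lowest, which B cells as the only source would not give if signals were proportional to RNA. This does not speak against a share of B cells beside other sources. The B cell signals of Ighm and H2-Aa, 46214 and 46174, also lay near the highest on that array, 58060, where the response was not tested. For the 17 B cell identity genes other than Ighm the highest ratio was 5.13 times the lowest, which leaves a B cell share open for them. Over 15 bright T cell genes above the detection level in both arrays, with 2 below it in B cells left out, the B cell signal had a median of 2.11% of the T cell signal, from 1.01% for Bcl11b to 74.2% for Cd2, or 73.2 times. That spread rests on Cd2, which a share of T cells does not account for, and for the other 14 genes it was 5.18 times, up to 5.26% for Zap70, so that a small share of T cells stays open for them. The stated purity above 98% leaves less than 2% for other cells, and all ratios of B cell genes lay above that, but no background was taken off. In the ES cell array Fcer2a and Ebf1 had signals of 109.1 and 94.6, against 218.6 and 138.1 in T cells. Bcl11b had 118.1 in ES cells, against 105 in B cells. The lowest ratios may thus hold background and do not show shares above 2%. A ratio of signals is also not a share of cells. Expression by the sorted cells themselves and unequal array response at low and at high signal were not tested.

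Of 15 macrophage markers, 14 had a positive and 1 a negative difference between the T cell and the B cell array, and 0 reached 4-fold. A further list of 22 macrophage genes, with 0 genes in another list, was written before its values were seen, and 14 of its 19 measured members (73.7%) lay in a range of width 1 that starts at 0.75 on the log2 scale, against 9.41% of all measured genes, with a median of 1.25; Vsig4 at -0.33 as a bound, Tlr4 at -0.96, Lgmn at -0.56, Apoe at 0.27 and Ms4a7 at 0.70 lay outside, 3 of them below 0. A higher share of macrophages in the T cell sample, whose stated purity was above 98%, is a candidate explanation that most of these values meet. Dendritic cell markers had a median of 1.34, however, so the values do not single out macrophages among myeloid cells. The neutrophil markers S100a8 and S100a9 lay at 1.17 and 0.86, but the 10 measured members of their list had a median of only 0.35. Scaling between the 2 arrays would need a general shift, and the median of all measured genes was -0.0484. The equal trimmed means of the deposited columns leave little room for such a shift, so this median does not test scaling. Expression by the T cells themselves cannot be told apart from macrophages with 1 array per population, and the robust SD over the further list was 0.177.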

How the results depend on the processing

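The alternatives were fixed before the data were examined, except that 8-fold and the agreement of probe sets were applied to the named genes only after the results had been seen, and without replicates none could leave out an array. No paired analysis was possible because each population had 1 array and no test was run. The 9 counts of genes at least 4-fold different stayed within 1.5 times under quantile normalization, scaling to the 75th percentile, no floor, a detection level at the 35th percentile, the mean of probe sets and leaving out s_at and x_at probe sets. At a threshold of 2-fold the counts were 2802 higher and 3041 lower in T cells against ES cells, 2635 and 3063 in B cells against ES cells, 995 and 707 in T cells against B cells, and 2598, 499 and 635 genes highest in ES cells, B cells and T cells. At 8-fold they were 665 and 522, 654 and 562, 112 and 87, and 454, 77 and 76, as the changed thresholds require. With the detection level at the 65th percentile, which raises the floor, 784 genes were lower in T cells and 799 in B cells than in ES cells, 166 higher in T cells than in B cells, 662 highest in ES cells and 117 highest in T cells. Requiring every probe set to differ at least 2-fold left 784 genes lower in T cells and 798 lower in B cells than in ES cells, and 656 highest in ES cells. The median of Polycomb repressive complex 2 in B cells against ES cells was -1.48 with scaling to the 75th percentile and -0.65 with the mean of probe sets. That of Polycomb repressive complex 1 was 0.14 with the mean of probe sets. The mean takes in probe sets below the detection level on both arrays as unchanged, and its part in these shifts was not tested. Medians of lists depend on the floor: of 75 list medians, 26 moved beyond their spread with no floor, 23 with the detection level at the 35th percentile and 30 of 74 at the 65th, against 16 with the mean of probe sets, 8 with scaling to the 75th percentile, 7 with quantile normalization and 3 without s_at and x_at probe sets. The pluripotency median was -6.54 in T cells and -6.43 in B cells with no floor and -4.04 and -4.15 at the 65th percentile. Signs changed for 8 medians with scaling to the 75th percentile, 6 with the mean of probe sets, 5 at the 65th percentile, 2 at the 35th, 2 with no floor, 2 without s_at and x_at probe sets and 1 with quantile normalization, all of them at most 0.55 in size as reported. Of 216 named differences of at least 4-fold, 216 kept their direction under quantile normalization and scaling to the 75th percentile, with no floor, at both other detection levels and with the mean of probe sets, and between 199 and 216 stayed at least 4-fold there. With no floor and at the other detection levels the direction could not change, since the order of a probe set's signals is kept. Under both scalings a change would have needed a shift of at least 4-fold. The kept directions are thus no evidence of stability under these alternatives. Without s_at and x_at probe sets 206 had a value, and 206 stayed at least 4-fold. At 8-fold 174 of the 216 were left, and 180 where every probe set had to differ at least 2-fold. That requirement also failed genes on probe sets below the detection level on both arrays, which enter as unchanged. The losses under it, here and in the counts, are thus not all disagreement between measured probe sets. Several measured probe sets were present for 96 of the 216. Of these, 35 had a probe set below 4-fold in the direction named, 20 below 2-fold and 2 of opposite sign. Signal over background limits the bounds, since 587 of the 1332 genes higher and 621 of the 1252 lower in T cells than in ES cells were below detection in the dimmer array.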

Other observations

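The 6 gene lists here were chosen after the data had been seen, so their values describe the arrays and test nothing, and members below the detection level enter the medians at that level. Of 15 measured glycolysis genes, 9 were at least 4-fold lower in T cells and 10 in B cells, with median log2 differences of -2.60 and -2.44. The hexokinase gene Hk1 was not lower, at 1.18 in T cells and 0.65 in B cells. Hk2, another hexokinase gene, had signals of 6402 in ES cells, 351 in B cells and 366 in T cells, and the glucose transporter gene Slc2a1 had 15556, 1915 and 1454. Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, stood apart with 4132 in ES cells, 1258 in B cells and 7522 in T cells, a difference of 2.58 between T cells and B cells. Of 13 measured junction and epithelial adhesion genes, 12 were at least 4-fold lower in each lymphocyte population, with a median of -4.28 in both, among them Cdh1, Epcam, Krt8 and Krt18. Heat shock genes had medians of -1.42 in T cells and -1.36 in B cells against ES cells, with 4 of 11 at least 4-fold lower in each.

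All 8 genes of the GIMAP family, GTPases of lymphocytes, were at least 4-fold higher in T cells and in B cells than in ES cells, with medians of 5.82 and 5.70 and of 0.04 between the lymphocytes. Of 17 interferon-stimulated genes, 14 were at least 4-fold higher in T cells than in ES cells, with a median of 3.44, and of 16 measured in B cells 12 were, with a median of 2.80. Between T cells and B cells their median was 0.36, with Ifit2 at 1.92 and Ifit1 at 1.80. Of 15 chemokine and lymphoid homing receptor genes, 12 were at least 4-fold higher in T cells than in ES cells, with a median of 4.12, and of 14 in B cells 8 were, with a median of 3.26. T cells were at least 4-fold above B cells for 5 of these genes, Cxcr6 at 4.80, Ccr9 at 3.27, Cxcr3 at 2.76, Ccr2 at least 2.63 and Ccr3 at 2.12, and at least 4-fold below them for 2, Ccr6 at -3.38 and Cxcr5 at -2.68, with a median of 0.55.

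Probe sets with no listed gene also differed between the arrays. Of 9160 such probe sets, 645 were at least 4-fold higher and 107 lower in T cells than in ES cells, 621 higher and 118 lower in B cells than in ES cells, and 100 higher and 64 lower in T cells than in B cells. Of 932 probe sets with several symbols the counts were 75 and 39, 77 and 36, and 6 and 12.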
